A study of Mus musculus with 8 samples.

How the data were processed

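Hearts were collected at E10.5 from mouse embryos of 2 genotypes, and total RNA was isolated from each with a column kit for small samples, per the labels' protocols. Libraries were made with a TruSeq stranded kit, which marks the strand of the RNA. Reads were demultiplexed with bcl2fastq and counted per gene with featureCounts on the mm10 build, per the submitters' processing notes. Tool versions, the aligner, the gene annotation and the strand setting of the counting are not given in the sources used here. The deposited values are raw counts per Entrez gene ID, whole numbers with no normalization, for 27179 genes in 8 hearts. The deposited table of the whole series and the 8 deposited files of single hearts hold identical counts, so the table was used. Because the strand setting is not given, reads of a gene and of an antisense or overlapping partner may be mixed in a count. Overlaps were searched for 70 genes, those named that passed the threshold and those chosen after their values were seen. Of these, 30 overlap another annotated gene and 10 another tested gene in the GRCm38.p6 RefSeq table. Other genes named here were not searched.

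Entrez IDs were matched to symbols and positions in the RefSeq gene table of GRCm38.p6, the assembly that mm10 stands for. A symbol was found for 25275 IDs; the 1904 IDs without a symbol held 1.05% of all counts and stayed in the tests under their IDs. Coordinates are from that table. No column of values was left unused for want of a matching sample. Groups were taken from the genotype in the labels: Kat6a WT with 5 hearts and Kat6a KO with 3.

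Computation used R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15 and pandas 2.3.3. Genes were filtered with edgeR's filterByExpr by group, which kept 15086, and libraries were scaled by trimmed mean of M values. The main test was edgeR's quasi-likelihood test (robust fit) of Kat6a KO against Kat6a WT over all 8 hearts with no covariate, with Benjamini-Hochberg adjustment and a threshold of 0.05. Log2 fold changes are Kat6a KO over Kat6a WT. Their standard error (SE) was taken from the test, as the absolute log2 fold change over the square root of its F statistic. CPM values use the scaled library sizes. The common dispersion was 0.00828, a biological coefficient of variation of 9.10%. With 19911803 to 34539787 counts per heart, this spread between hearts, rather than counting error, sets the error of moderately expressed genes, while counting error adds to that of genes near 1 CPM.

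Before the data were examined, 30 gene lists were fixed from the tissue and the gene: heart cell types and cell types that could be carried along, cardiac and signalling pathways, complex subunits, neighbours of Kat6a and genes that mark RNA handling. A list of sex-linked genes was read per heart only. Lists with at least 5 tested members were tested with limma's camera (preset correlation 0.01, on log2 CPM with a prior count of 2), with Benjamini-Hochberg adjustment over the 30 lists. Camera with an estimated correlation passed 0 lists (5 had an unadjusted p under 0.05), and fry, which tests whether the genes of a set move on balance in a single direction, passed 6: cardiac transcription factors, second heart field, epicardium, sarcomere, macrophages, and glycolysis and hypoxia. Members past the threshold were counted over all genes and adjusted over the list alone. Hbb-bt and Ahsp of the erythroid list were not analysed here. The genes named were fixed by rule: Kat6a; the 10 largest increases and 10 largest decreases among genes past the threshold with an average log2 CPM of at least 1, no overlap between the groups, a proper symbol and no sex linkage; up to 4 members of smallest p from each list, or up to 2 where no member passed; and Tbx1, Tbx5, Wt1 and Aldh1a2 in any case. Of the genes this rule selects, 1 is not reported here.

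The gene test was checked on simulated counts for 14936 genes with the means and library sizes of these hearts, 50 genes changed at each of 4 sizes. It recovered 42% of 1.25-fold, 80% of 1.5-fold, 98% of 2-fold and 100% of 4-fold changes, and 12 of 172 calls (6.98%) were false. The list test recovered 20 of 20 simulated lists of 25 genes shifted by 0.2 on the log2 scale and called 0 of 200 unshifted lists. Changed genes and the genes of all lists were drawn from those with a mean of at least 2 CPM. The recovery rates therefore do not cover genes under that level. Counts of each gene were drawn independently and lists were random genes. The simulation therefore cannot show how often lists are called falsely where their genes vary together between hearts.

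Alternatives fixed in advance were DESeq2, limma voom with quality weights, DESeq2 size factors or upper-quartile scaling within edgeR, no count filter, a filter at 1 CPM in 3 hearts, a fit without robust moderation, a replicate block, Xist or mean erythroid expression as a covariate, leaving out erythroid genes, and leaving out each heart in turn. A fit without the 2 hearts that had Xist RNA was added after the data were seen.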

Results

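RNA was sequenced from 8 whole mouse hearts taken at E10.5, an embryonic day when the heart has looped, its chambers are forming and the epicardium is spreading over its surface. By the labels, 5 hearts were wild type (Kat6a WT) and 3 had lost both alleles of Kat6a (Kat6a KO). Kat6a, also called Moz, encodes a histone acetyltransferase of the MYST family. Each heart has its own library, and the deposited values are whole-number read counts per gene. Total counts were 29572508, 20817852, 34539787, 22924042 and 24694940 in Kat6a WT replicates 1 to 5, and 30033097, 19911803 and 22082041 in Kat6a KO replicates 1 to 3. The 20 most abundant genes took between 8.80% and 9.25% of the counts of a heart. All 28 pairs of libraries differed by more than sampling noise, with a chi-square per degree of freedom of 8.74 to 33.0, so each counted as a separate sample. The labels do not give the litter, the dissection day or the sex of the embryos, and p-values measure the spread between these hearts. The sample descriptions number all Kat6a KO hearts ahead of all Kat6a WT hearts. What that order stands for is not stated, and an effect of it cannot be told apart from genotype. Values are given below as CPM, read counts scaled to the size of the library, mean ± SD, with n = 5 for Kat6a WT and n = 3 for Kat6a KO.

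The count of the targeted gene did not separate the groups. Kat6a (Entrez gene 244349) lay on chromosome 8 from 22859442 to 22943259 (mm10) and had 138, 144, 143, 141 and 156 CPM in Kat6a WT replicates 1 to 5, against 141, 133 and 137 CPM in Kat6a KO replicates 1 to 3. Its log2 fold change was -0.08 ± 0.05 (SE; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.529). A count over the whole gene does not show which exons the reads came from, and the part removed by the allele is not given in the sources used here, so this count does not check the genotype labels. The groups are therefore taken as labelled throughout. RNA of Xist, transcribed from the inactive X chromosome of female cells, stood at 307 CPM (of total counts, for sex-linked genes) in Kat6a WT replicate 4 and 301 CPM in Kat6a WT replicate 5, and at no more than 0.372 CPM in the other 6 hearts. Ddx3y, on the Y chromosome, stood at 63.5 to 73.7 CPM in those 6 hearts and at no more than 0.0810 CPM in Kat6a WT replicates 4 and 5. Every heart labelled Kat6a KO thus had Y-linked RNA, and the group labelled Kat6a WT was mixed.

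The comparison asks what loss of Kat6a changes in the transcriptome of the heart at this stage; the title of the series places it in a study of histone acetylation and the epicardial lineage. In hearts labelled Kat6a KO, 7 of 15 epicardial markers, 7 of 24 cardiac transcription factors and 4 of 17 second heart field genes fell, and 1 gene of each of these lists rose. Of the genes of the sarcomere, of glycolysis and hypoxia, and of macrophages, 7 of 29, 7 of 23 and 6 of 14 rose and 0 fell. All 6 lists passed limma camera with its preset correlation, and none did with an estimated correlation (adjusted p = 0.208 to 0.269). Nkx2-6 (chromosome 14, 69171802 to 69175540), a homeobox gene of the pharyngeal region, fell from 3.05 ± 1.20 to 0.253 ± 0.112 CPM. Hand1, a transcription factor of the outer curvature of the ventricles, fell from 88.2 ± 10.47 to 43.0 ± 2.42 CPM. Wt1, which marks the epicardium, fell from 51.9 ± 2.99 to 37.0 ± 3.12 CPM. Tnni2 (chromosome 7, 142441816 to 142444410), the fast skeletal muscle form of troponin I, rose from 18.7 ± 1.09 to 56.2 ± 7.40 CPM, and Adgre1, which encodes the macrophage antigen F4/80, rose from 0.396 ± 0.248 to 2.32 ± 0.136 CPM.

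Of 15086 genes tested, 403 passed an adjusted p of 0.05 (edgeR quasi-likelihood test, Benjamini-Hochberg), with 217 higher and 186 lower in Kat6a KO. Most changes were small: 268 of the 403 genes (66.5%) changed by less than 1.5-fold, while 32 rose and 33 fell by at least 2-fold. In 392 of them the 3 Kat6a KO values lay entirely above or below the 5 Kat6a WT values. Over all genes tested this held for 1446 (9.59%), where chance gives 3.57%. The number of genes depended on single hearts: it was 194 without Kat6a KO replicate 1 and 263 without Kat6a KO replicate 3. Without the 2 hearts that had Xist RNA it was 281, of which 165 were higher and 116 lower, and 233 of these were among the 403.

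**Figure D1:**
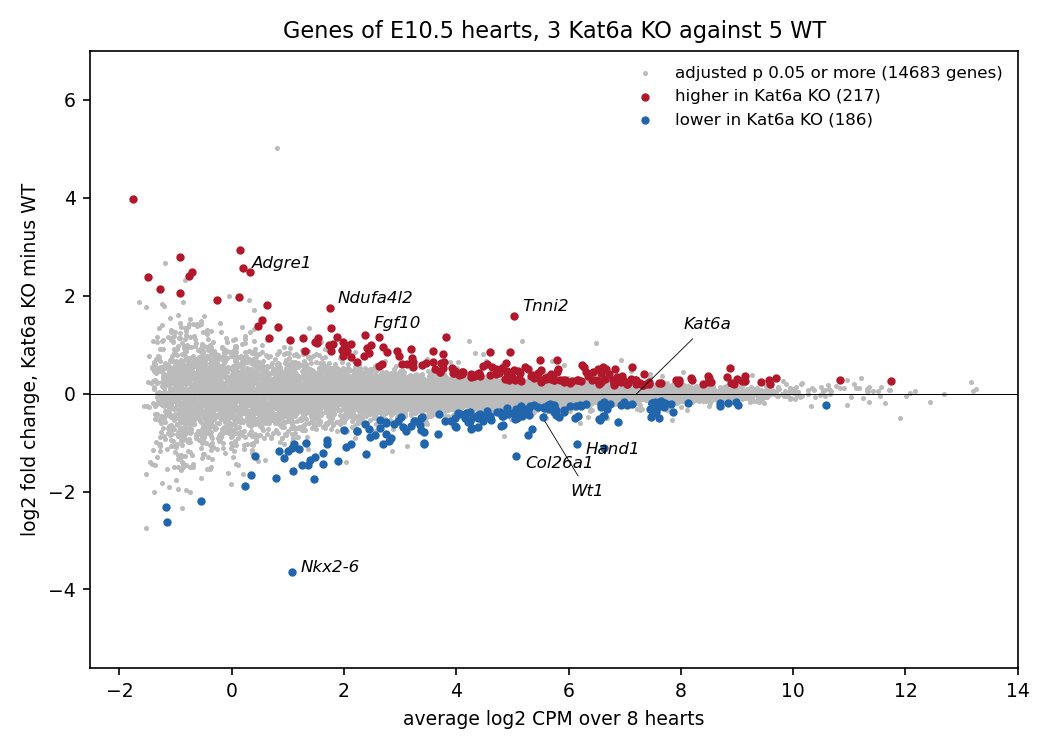
Each point is 1 of 15086 genes, with the average log2 CPM over the 8 hearts on the x axis and the log2 fold change of Kat6a KO over Kat6a WT on the y axis. Red points are the 217 genes that rose and blue points the 186 that fell at an adjusted p under 0.05 (edgeR quasi-likelihood test); Kat6a itself lies at -0.08.

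The genes of largest change are given for those past the threshold with an average log2 CPM of at least 1 and no overlap between the values of the 2 groups, without sex-linked genes, unnamed genes and predicted genes known by a Gm or Rik symbol. Under these limits the 10 largest increases were those of Ndufa4l2 (log2 fold change 1.75), Tnni2 (1.58), Trpm3 (1.35), Fgf10 (1.20), Itgal (1.15), Csf1r (1.15), Neurl3 (1.14), Hhatl (1.14), Pik3r6 (1.10) and Parp10 (1.05). Ndufa4l2, a mitochondrial protein induced by hypoxia, rose from 1.77 ± 0.481 to 5.89 ± 0.890 CPM. Fgf10, a growth factor of the second heart field, rose from 3.47 ± 0.779 to 7.97 ± 0.276 CPM. Itgal and Csf1r encode a leukocyte integrin subunit and the receptor of the macrophage growth factor. The 10 largest decreases under the same limits were those of Nkx2-6 (-3.63), Gal (-1.75), Igsf11 (-1.45), Nup62cl (-1.45), Hkdc1 (-1.44), Aqp5 (-1.39), Dock2 (-1.35), Angptl7 (-1.30), Col26a1 (-1.28) and Lhx9 (-1.24). Col26a1, a collagen gene, fell from 42.9 ± 3.57 to 17.8 ± 1.73 CPM. Gal, which encodes the neuropeptide galanin, fell from 3.53 ± 0.682 to 1.04 ± 0.116 CPM. Standard errors ranged from 0.08 for Tnni2 to 0.42 for Nkx2-6. Single hearts decided some calls in the edgeR quasi-likelihood test: without Kat6a KO replicate 3 the adjusted p was 0.0580 for Hhatl, 0.0703 for Itgal and 0.0799 for Pik3r6, and the calls of Parp10, Angptl7 and Csf1r were lost on leaving out any of 3, 5 and 6 single hearts, with an adjusted p of up to 0.121, 0.127 and 0.152. Angptl7 and Csf1r also lost theirs without the 2 hearts that had Xist RNA (adjusted p = 0.0896 and 0.193, edgeR quasi-likelihood test) and with Xist RNA as a covariate (0.0673 and 0.162). Angptl7 lies within Mtor, and Dock2 and Hhatl overlap Insyn2b and Klhl40, so their counts are uncertain where reads could be shared.

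Some epicardial markers fell. Of 15 markers tested, 7 fell, 1 rose and 7 did not pass; adjusted over the list alone, 10 fell and 1 rose. Lrrn4 fell by 0.51 ± 0.06 (SE) on the log2 scale, from 77.7 ± 4.12 to 54.6 ± 3.11 CPM. Bnc1, the gene of the zinc finger protein basonuclin, fell by 0.72 ± 0.10, and Wt1 (chromosome 2, 105126529 to 105173614) fell by 0.49 ± 0.07. Krt19, a keratin gene, went the other way and rose by 0.42 ± 0.07, from 38.8 ± 3.52 to 51.9 ± 1.70 CPM. Aldh1a2, the enzyme that makes retinoic acid in the epicardium, had a log2 fold change of -0.37 ± 0.16 that did not pass (edgeR quasi-likelihood test, adjusted p = 0.344), and neither did that of Tbx18 (-0.25 ± 0.08, adjusted p = 0.127). The median over the list was -0.37 (limma camera, adjusted p = 2.46e-07), and the call was lost with an estimated correlation (adjusted p = 0.208 with an estimated correlation). Without the 2 hearts that had Xist RNA, 5 markers fell and 1 rose.

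Some cardiac transcription factors and second heart field genes fell too. Of 24 cardiac transcription factors, 7 fell, 1 rose and 16 did not pass; adjusted over the list alone, 13 fell and 1 rose. Hand1 (chromosome 11, 57828713 to 57832147) fell by 1.04 ± 0.09 (SE) on the log2 scale. Srf, which drives muscle gene transcription with its cofactors, fell by 0.21 ± 0.04, from 239 ± 4.79 to 206 ± 6.83 CPM. Gata4 fell by 0.19 ± 0.04. Tbx5 had a log2 fold change of -0.21 ± 0.07 that did not pass (edgeR quasi-likelihood test, adjusted p = 0.195). Of 17 genes of the second heart field and pharyngeal region, 4 fell, 1 rose and 12 did not pass; adjusted over the list alone, 5 fell and 1 rose. Besides Nkx2-6, Foxc1 fell by 0.63 ± 0.11 and Tcf21 by 0.41 ± 0.09, while Fgf10 rose by 1.20 ± 0.17. The remaining gene that fell was Wnt11, given below with the Wnt pathway. Tcf21 is also counted among the epicardial markers that fell. It shares 2881 bases with the tested gene Gm10824, so its count is uncertain where reads could be shared. Tbx1, a gene of the pharyngeal region whose loss affects the outflow tract, was under the count filter, with 2 to 41 counts in Kat6a WT and 1 to 11 in Kat6a KO hearts. The medians were -0.12 for cardiac transcription factors (limma camera, adjusted p = 0.000189; adjusted p = 0.208 with an estimated correlation) and -0.34 for the second heart field (adjusted p = 0.00131; adjusted p = 0.208 with an estimated correlation). In the edgeR quasi-likelihood test, Gata4 lost its call without Kat6a KO replicate 1 or 2 (adjusted p up to 0.129) and Tcf21 on leaving out any of 6 single hearts (up to 0.120). Without the 2 hearts that had Xist RNA, 3 cardiac transcription factors fell, and in the second heart field list 3 genes fell and 1 rose; Gata4 and Tcf21 were not past the threshold (adjusted p = 0.0961 and 0.127, edgeR quasi-likelihood test).

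Some genes of the contractile apparatus rose. Of 29 sarcomere and contraction genes, 7 rose, 0 fell and 22 did not pass; adjusted over the list alone, 14 rose. Myoz2, a protein of the sarcomeric Z-disc, rose by 0.62 ± 0.10 (SE) on the log2 scale, from 24.6 ± 3.23 to 37.6 ± 3.87 CPM. Csrp3, another Z-disc protein, rose by 0.30 ± 0.05, from 473 ± 20.6 to 584 ± 30.8 CPM. Tpm1, encoding a tropomyosin, rose by 0.25 ± 0.05, from 3190 ± 147 to 3801 ± 44.9 CPM. The myosin light chain gene Myl3 rose by 0.27 ± 0.06, and that call was lost without Kat6a KO replicate 1 or 3 (edgeR quasi-likelihood test, adjusted p up to 0.105). The median over the list was 0.13 (limma camera, adjusted p = 1.27e-07; adjusted p = 0.254 with an estimated correlation). Immediate early and heat shock genes, which respond to the handling of tissue, had a median of 0.28, in the direction of this list and of the endothelial and oxidative phosphorylation lists below, with 12 of 15 above 0 and 0 past the threshold (list adjusted p = 0.121, limma camera). Without the 2 hearts that had Xist RNA, 4 sarcomere genes rose and 0 fell, and Myl3 did not pass (adjusted p = 0.0653, edgeR quasi-likelihood test).

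Some glycolytic and hypoxia-induced genes rose as well. Of 23 such genes, 7 rose, 0 fell and 16 did not pass; adjusted over the list alone, 14 rose and 1 fell. Bnip3, a mitophagy receptor induced by hypoxia, rose by 0.41 ± 0.05 (SE) on the log2 scale, from 94.1 ± 5.78 to 125 ± 4.87 CPM. Pdk1, a kinase that holds back the entry of pyruvate into the mitochondrial citric acid cycle, rose by 0.33 ± 0.06, from 266 ± 22.2 to 333 ± 13.04 CPM. The liver-type phosphofructokinase gene Pfkl rose by 0.22 ± 0.05 and the collagen prolyl hydroxylase gene P4ha1 by 0.24 ± 0.05. The median was 0.20 (limma camera, adjusted p = 1.27e-07; adjusted p = 0.269 with an estimated correlation), beside a median of 0.28 for immediate early and heat shock genes. In the edgeR quasi-likelihood test, Pfkl lost its call without Kat6a KO replicate 2 (adjusted p = 0.0864) and P4ha1 without Kat6a KO replicate 1 or 2 (adjusted p up to 0.134). Without the 2 hearts that had Xist RNA, 4 genes rose and 0 fell, and P4ha1 did not pass (adjusted p = 0.0621, edgeR quasi-likelihood test).

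Some macrophage and leukocyte markers rose from low levels. Of 14 markers, 6 rose, 0 fell and 8 did not pass. Adjusted over the list alone, 9 rose. All 14 had a log2 fold change above 0, though that of Coro1a was only 0.002. Adgre1 rose by 2.57 ± 0.40 (SE) on the log2 scale. C1qa and C1qb, which encode chains of the complement protein C1q, rose by 2.48 ± 0.46 and 1.81 ± 0.31, from 0.463 ± 0.399 to 2.50 ± 0.293 CPM and from 0.794 ± 0.185 to 2.80 ± 1.21 CPM. Laptm5, a lysosomal protein of blood cells, rose by 0.87 ± 0.14, from 9.19 ± 1.98 to 16.7 ± 0.538 CPM. The median over the list was 1.01 (limma camera, adjusted p = 2.77e-09; adjusted p = 0.208 with an estimated correlation), and that of immediate early and heat shock genes 0.28. Mean log2 CPM of the erythroid markers, a measure of the blood in each heart, was 6.60 ± 0.87 in Kat6a WT and 6.56 ± 0.39 in Kat6a KO (exact permutation test, two-sided, p = 0.982, n = 5 and n = 3). With Xist RNA as a covariate C1qa had an adjusted p of 0.0521 (edgeR quasi-likelihood test), and without the 2 hearts that had Xist RNA, 5 markers rose and 0 fell.

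**Figure D2:**
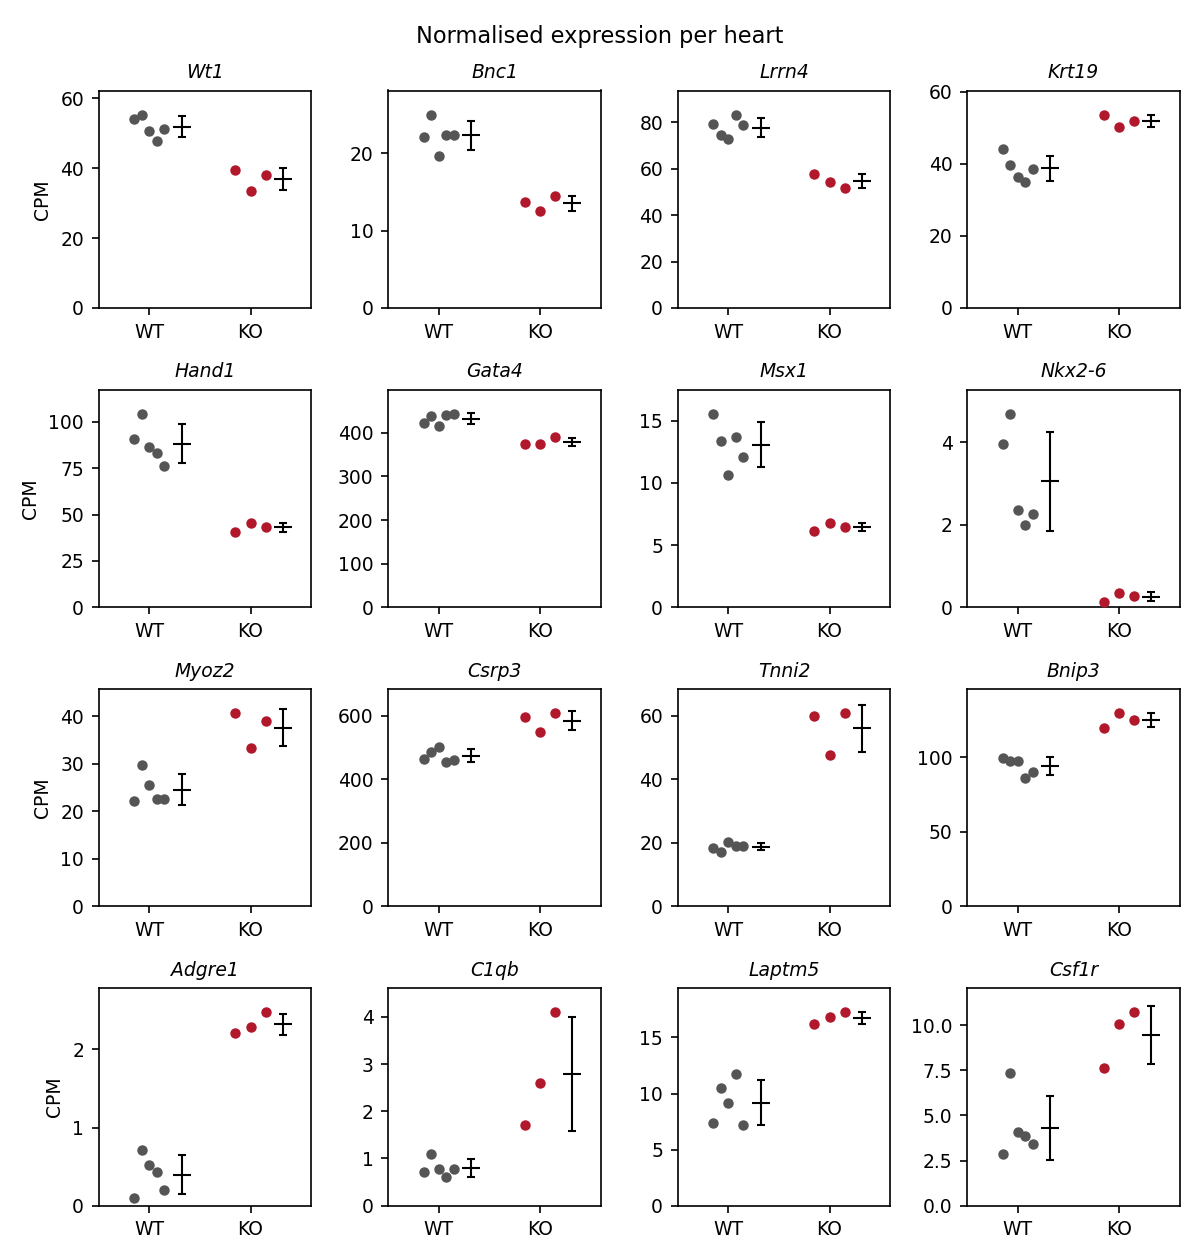
CPM of 16 genes in each heart, with Kat6a WT hearts in grey and Kat6a KO hearts in red, and the mean ± SD of each group as a bar beside its points (n = 5 and n = 3). Every y axis starts at 0; Hand1 lies near 88.2 CPM in Kat6a WT and 43.0 CPM in Kat6a KO, and Tnni2 near 18.7 and 56.2 CPM.

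Endothelial and cushion genes moved both ways. Of 24 endothelial and endocardial markers, 3 rose, 1 fell and 20 did not pass; adjusted over the list alone, 7 rose and 2 fell. Robo4, a guidance receptor of endothelial cells, rose by 0.93 ± 0.19 (SE) on the log2 scale, and Pecam1 and Tie1 each rose by 0.20 ± 0.05. Npr3, a natriuretic peptide receptor expressed in endocardium, fell by 0.49 ± 0.06, from 219 ± 14.98 to 156 ± 12.8 CPM. It shares 866 bases with the tested gene Gm5144. Of 22 genes of the endocardial cushions and their matrix, 3 fell, 1 rose and 18 did not pass; adjusted over the list alone, 6 fell and 2 rose. The homeobox gene Msx1 fell by 1.01 ± 0.13, from 13.1 ± 1.84 to 6.48 ± 0.327 CPM, while its paralog Msx2 rose by 0.41 ± 0.11. Twist1 fell by 0.48 ± 0.07 and Fbln1, encoding a matrix protein, by 0.20 ± 0.05. Medians were 0.13 for endothelium (limma camera, adjusted p = 0.00936; adjusted p = 0.344 with an estimated correlation) and -0.13 for cushions (adjusted p = 0.0368; adjusted p = 0.734 with an estimated correlation), and the cushion list lost its call without Kat6a WT replicate 2 (median -0.05, adjusted p = 0.351) or Kat6a KO replicate 2 (median -0.09, adjusted p = 0.131). In the edgeR quasi-likelihood test Robo4 lost its call without Kat6a KO replicate 3 (adjusted p = 0.0833), and Pecam1, Tie1, Fbln1 and Msx2 lost theirs on leaving out any of 4 to 7 single hearts (adjusted p up to 0.105, 0.188, 0.143 and 0.265). Leaving out the 2 hearts that had Xist RNA, 1 endothelial marker rose and 1 fell, and 2 cushion genes fell and 0 rose; the adjusted p was then 0.0830 for Pecam1, 0.0990 for Tie1, 0.148 for Fbln1 and 0.167 for Msx2.

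Several pathway lists were called with few or no changed members. In the retinoic acid pathway 1 of 14 genes fell and 0 rose, over all genes and also adjusted over the list alone: Aldh1a1, a retinaldehyde dehydrogenase, by 0.68 ± 0.11 (SE) on the log2 scale, from 24.1 ± 3.66 to 15.04 ± 0.915 CPM. In the Wnt pathway 1 of 18 genes fell, Wnt11, by 0.27 ± 0.07, and adjusted over the list alone 4 fell and 1 rose. Of 9 developmental timing genes 2 fell, or 3 adjusted over the list alone: Arid3b, by 0.32 ± 0.06, and Trim71, a target of the let-7 microRNA, by 0.47 ± 0.11. Of 28 proliferation genes and 25 oxidative phosphorylation genes, 0 passed over all genes and 0 adjusted over the list alone, and 24 of the 28 had a log2 fold change under 0 and 22 of the 25 above 0. Mcm2 had -0.16 ± 0.05 (edgeR quasi-likelihood test, adjusted p = 0.0780) and Cox6c 0.18 ± 0.07 (adjusted p = 0.240). Medians (limma camera) were -0.16 for retinoic acid (adjusted p = 0.0130; adjusted p = 0.269 with an estimated correlation), -0.14 for Wnt (adjusted p = 0.0368; adjusted p = 0.254 with an estimated correlation), -0.08 for developmental timing (adjusted p = 0.0111; adjusted p = 0.501 with an estimated correlation), -0.06 for proliferation (adjusted p = 0.00310; adjusted p = 0.767 with an estimated correlation) and 0.08 for oxidative phosphorylation (adjusted p = 0.00498; adjusted p = 0.881 with an estimated correlation). Without the 2 hearts that had Xist RNA, 4 of these 5 calls were lost, with an adjusted p (limma camera) of 0.0730 for retinoic acid, 0.261 for Wnt, 0.0923 for proliferation and 0.473 for oxidative phosphorylation. Leaving out a single heart ended the calls of retinoic acid (Kat6a KO replicate 2, adjusted p = 0.0850), Wnt (any of 4 hearts, up to 0.259, where the median was -0.07) and oxidative phosphorylation (Kat6a WT replicate 4 or Kat6a KO replicate 3, up to 0.110, where it was 0.04), and those of Wnt11 (any of 6 hearts, up to 0.220) and Trim71 (Kat6a KO replicate 1 or 3, up to 0.0992) in the edgeR quasi-likelihood test. The median of developmental timing ran from -0.18 to -0.05 over the alternatives.

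**Figure D3:**
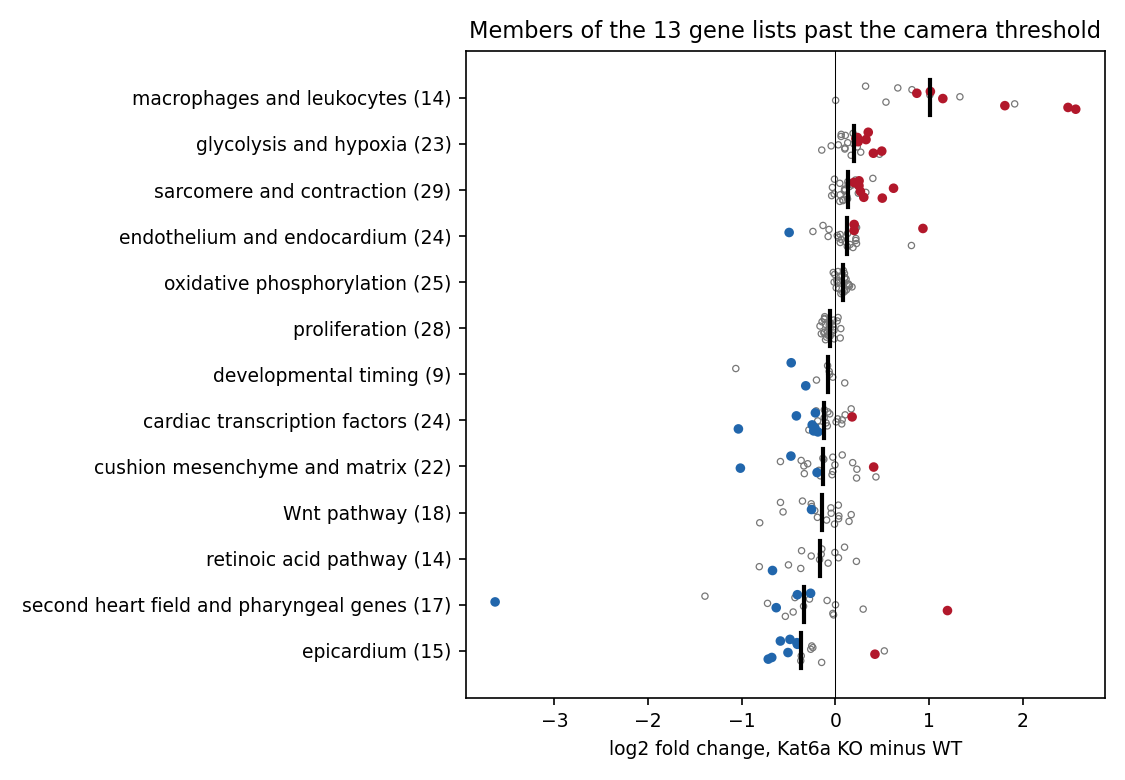
Log2 fold change, Kat6a KO over Kat6a WT, of each tested member of the 13 gene lists past the limma camera threshold, with the number of members in brackets and the list's median as a black bar. Filled red and blue points are members that rose or fell at an adjusted p under 0.05 over all genes, and open points are the rest; the medians run from -0.37 for epicardium to 1.01 for macrophages.

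The other 17 of 30 lists did not pass (limma camera), though some of their members did. Among atrial genes the myosin light chain gene Myl1 rose by 0.40 ± 0.06 (SE) on the log2 scale (list adjusted p = 0.717). The atrial list passed without the 2 hearts that had Xist RNA (limma camera, adjusted p = 0.0481), and 3 of its members then rose. Among ventricular genes Irx4 fell by 0.25 ± 0.06, Irx1 by 0.44 ± 0.10, and Myl3 rose (list adjusted p = 0.842). Among genes of the conduction system Irx3 fell by 0.45 ± 0.07 and Kcnj5 by 0.19 ± 0.05 (list adjusted p = 0.877). In the Notch list Mfng, a sugar transferase that modifies Notch, rose by 1.06 ± 0.21 (list adjusted p = 0.778). In the FGF list Fgf10 rose and Spry4, an inhibitor of FGF signalling, fell by 0.39 ± 0.10 (list adjusted p = 0.799). No member passed in the remaining lists: subunits of the MOZ and HBO1 complexes (adjusted p = 0.877), Hox genes (0.778), T-box genes (0.842), neural crest (0.965), erythroid cells (0.877), megakaryocytes (0.866), liver and foregut endoderm (0.626), neurons and neural tube (0.865), p53 targets and CDK inhibitors (0.906), BMP and TGF-beta (0.778), immediate early and heat shock genes (0.121) and neighbours of Kat6a (0.717). The list of immediate early and heat shock genes passed under 3 alternatives (lowest adjusted p = 0.00709, limma camera), and over the splits of the hearts its camera p was as small in a share of 0.625 (exact permutation p). In 8 of the 17 lists the median, the mean and the camera direction differed in sign, so no direction is given. Among the members, Kat6b, the closest paralog of Kat6a, had a log2 fold change of 0.21 ± 0.08 (edgeR quasi-likelihood test, adjusted p = 0.182), and Cdkn1c, a cell cycle inhibitor, had -0.18 ± 0.05 (adjusted p = 0.0662). Only 8 of 39 Hox genes and 5 of 16 liver and foregut genes had enough counts to be tested, so changes in the rest were not detectable at this depth. Several of the single-gene calls rested on individual hearts (edgeR quasi-likelihood test): Irx1 lost its call without Kat6a KO replicate 1 (adjusted p = 0.157), Mfng without Kat6a KO replicate 2 or 3 (up to 0.0657), and Irx4, Kcnj5 and Spry4 on leaving out any of 6 or 7 single hearts (up to 0.232, 0.126 and 0.191). In the fit without the 2 hearts that had Xist RNA, Irx1, Mfng, Kcnj5 and Spry4 lost their calls (adjusted p = 0.0599, 0.0546, 0.119 and 0.181, edgeR quasi-likelihood test).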

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

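Of the 2 tests of the macrophage markers given here, the fit with erythroid expression as a covariate was fixed in advance, but what it would show under each explanation was written after the result was seen. The fit without the 2 hearts that had Xist RNA was chosen after the data were seen. Among 73 quantities read in the 5 Kat6a WT hearts, 4 had a highest or lowest heart whose gap to the nearest other heart exceeded 0.71 of the range (Dixon's test), where chance gives about 3.65. Csf1r was highest in Kat6a WT replicate 2, at 7.33 CPM against 2.84 to 4.06 in the other 4 hearts (gap 0.728 of the range), close to the lowest Kat6a KO heart at 7.63 CPM. Pecam1 was highest in the same heart, at 150 against 136 to 139 CPM (gap 0.791). Hhatl was also highest there, at 2.06 against 1.51 to 1.57 CPM (gap 0.895). Afp, a marker of liver and yolk sac endoderm, was highest in Kat6a WT replicate 5, at 0.566 CPM against 0 to 0.0677 in the others (gap 0.880). In Kat6a KO replicates 1 to 3 Afp stood at 1.04, 0.661 and 12.1 CPM, and its log2 fold change of 5.01 ± 1.41 did not pass (edgeR quasi-likelihood test, adjusted p = 0.176).

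The rise of macrophage and leukocyte markers, of which Csf1r is a member, had a median log2 fold change of 1.01. More blood left in the Kat6a KO hearts is argued against as the whole cause: with mean erythroid log2 CPM as a covariate the median was 1.09. The mix of sexes in Kat6a WT is argued against in the same way, with a median of 0.988 without the 2 hearts that had Xist RNA, although in that fit the erythroid list was itself called higher, with a median of 0.32 (limma camera, adjusted p = 0.00978). More macrophages in the Kat6a KO hearts, leukocytes that do not follow erythroid content, and higher expression per cell stay open, and these bulk libraries do not separate them. The genotype may be the source of the difference, as a hypothesis, since the labels give no litter or dissection batch against which to test it.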

How the results depend on the processing

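The fit without the 2 hearts that had Xist RNA was chosen after the data were seen. Under other choices of test, scaling and filter, the number of changed genes ran from 339 (no robust moderation) to 580 (DESeq2, which called all 403). It was 284 with Xist as a covariate, of which 228 were among the 403, and 194 (without Kat6a KO replicate 1) to 496 (without Kat6a WT replicate 2) when 1 heart was left out; it was 263 without Kat6a KO replicate 3. With the replicate block the count was 181, of which 150 were among the 403. Hearts of the same number had correlations of 0.09, -0.23 and -0.07 in their deviations from the group means. Those of different numbers ran from -0.20 to 0.22. There was thus no sign of pairing by number, but so few hearts cannot exclude a shared litter or day. The count of lists stayed at 10 to 14 in every gene-level alternative, but was 0 with an estimated correlation and 6 with fry. The erythroid list was uncalled in the main test, with a camera direction below the other genes. It was called higher with the replicate block (limma camera, adjusted p = 0.00270), with Xist as a covariate (adjusted p = 0.00834) and without the 2 hearts that had Xist RNA (adjusted p = 0.00978). All of these settings set aside or adjust for the same 2 hearts. Kat6a WT replicates 4 and 5 have no Kat6a KO heart of the same number, so the block takes them out of the comparison too. Their mean erythroid log2 CPM was 7.77 and 6.84, against 5.68, 5.80 and 6.91 in Kat6a WT replicates 1 to 3 and 6.17 to 6.96 in Kat6a KO. The source of their erythroid content was not tested. The atrial list came to pass with the replicate block (adjusted p = 0.0293) and without the 2 hearts that had Xist RNA, the list of immediate early and heat shock genes with limma voom and without Kat6a KO replicate 2 or 3, and the liver list without a count filter (adjusted p = 0.0121). Of 17 uncalled lists, 11 changed camera direction under some alternative. Over 2658 pairs of result and alternative, 2409 stayed on the same side of the threshold (a count, within 1.5-fold). A further 216 fell below it or were counts lower by more, and 30 came to pass it or were counts higher by more. The last 3, all of the erythroid list, passed in the other direction. Uncalled lists turned in 38 pairs, of which the 35 that did not pass are among the 2409. Of 60 named genes past the threshold, 30 passed under all 20 alternatives, and 46 passed without the 2 hearts that had Xist RNA. The Kat6a log2 fold change stayed between -0.10 and -0.05. The per-heart files were not run as another source of the counts, because they hold identical values. Depth left genes under the count filter untested, and in simulation 42% of 1.25-fold changes were recovered among genes of at least 2 CPM.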

Other observations

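The genes of this paragraph and the next were chosen after their values were seen, as were the tests below that leave out the hearts with Xist RNA and those on the position of genes. They are given singly, since no list of skeletal muscle genes was fixed or tested. Tnnt3, fast skeletal troponin T, rose by 0.81 ± 0.12 (SE) on the log2 scale, from 10.6 ± 1.14 to 18.4 ± 3.86 CPM (SD, n = 5 and n = 3). Casq1, the skeletal calsequestrin, rose by 0.52 ± 0.06, from 402 ± 33.4 to 576 ± 43.0 CPM. Ckm, muscle creatine kinase, rose by 1.00 ± 0.22 and Neb, nebulin, by 0.86 ± 0.20 (edgeR quasi-likelihood test, adjusted p = 0.0123 and 0.0173). Ckm lost its call without Kat6a KO replicate 1 or 3 (adjusted p up to 0.103) and Neb without Kat6a KO replicate 2 or 3 (up to 0.171). Neb also lost its call without the 2 hearts that had Xist RNA (adjusted p = 0.0855, edgeR quasi-likelihood test), with Xist RNA as a covariate (0.102) and with limma voom (0.0567). Tnni2 and Tnnt3 (142498771 to 142516213) lie on chromosome 7 to the side of the imprinted genes H19 (142575530 to 142578146) and Igf2 (142650768 to 142666816), not between them. Whether their rise is linked to these genes was not tested. Igf2os, a noncoding RNA that runs antisense to Igf2 (chromosome 7, 142659680 to 142670356), fell by 1.12 ± 0.06, from 124 ± 6.61 to 57.5 ± 2.07 CPM (edgeR quasi-likelihood test, adjusted p = 9.73e-11). Igf2 had a log2 fold change of -0.17 ± 0.05 and H19 of 0.10 ± 0.05, and neither passed (adjusted p = 0.0710 and 0.351). Igf2os shares 7137 bases with Igf2 and Tnnt3 shares 8001 with Prr33, so these counts are uncertain without the strand setting.

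Irx5, a homeobox gene, fell by 0.40 ± 0.07 (SE) on the log2 scale, from 38.6 ± 2.73 to 29.2 ± 0.688 CPM. On chromosome 2 the neighbours Commd3 (18672435 to 18676231) and Bmi1 (18677018 to 18686629) rose together, by 0.50 ± 0.08 and 0.54 ± 0.07 on the log2 scale. Bmi1, a Polycomb group gene, went from 31.9 ± 2.43 to 46.1 ± 1.17 CPM. Cdkn2a, a gene that Bmi1 represses in many cells, had 1 to 7 counts in Kat6a WT and 1 to 11 in Kat6a KO hearts and was not tested.

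Chance as the source of the gene count was tested with all 56 splits of the 8 hearts into 3 and 5: the real split gave 403 genes, the highest other split 7, and 49 of 55 other splits 0 (edgeR quasi-likelihood test), so 1 of the 56 splits, the real 1, gave as many. For the lists, 1 of the 56 splits gave as many as the real 13, but the highest other gave 12 and the median of the others was 6, so a call by camera with the preset correlation is weak evidence for a single list. Over the splits, the camera p of a list was as small in a share under 0.05 for 5 of the 13 lists: sarcomere (exact permutation p = 0.0179, the smallest that 56 splits give), cardiac transcription factors (exact permutation p = 0.0179), and epicardium, macrophages, and glycolysis and hypoxia (exact permutation p = 0.0357 each). It was not for the other 8, which ranged from an exact permutation p of 0.0714 for the second heart field to 0.357 for oxidative phosphorylation. These exact permutation p-values are not adjusted over the lists, so a share under 0.05 does not by itself set the 5 lists apart.

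The fall of the epicardium list had a median of -0.37. More female hearts in Kat6a WT is argued against as its cause, since the median was -0.361 without the 2 hearts that had Xist RNA. A smaller epicardial share that lowers all markers alike is argued against too: the 15 log2 fold changes differed by more than their errors (Cochran's Q against a chi-square distribution, which takes the genes as independent, n = 15 genes, heterogeneity p = 3.10e-28), and those of the 14 without Krt19 still did (heterogeneity p = 0.000143, pooled change -0.43). A smaller epicardial share stays open where other cells also express some markers, and so does lower expression per epicardial cell. The change may follow from the genotype, as a hypothesis.

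The sarcomere and the glycolysis and hypoxia lists rose by medians of 0.13 and 0.20. A bias with gene length is argued against: the median of both lists together was 0.142 after a smooth trend on length was removed. More female hearts in Kat6a WT is argued against as well, with a median of 0.124 without the 2 hearts that had Xist RNA. A later stage of the Kat6a KO embryos cannot be told apart from an effect of the genotype: the log2 ratio of the embryonic globins Hbb-bh1 to Hbb-y, which falls as primitive red cells mature, was -1.28 ± 0.07 (SD, n = 5) in Kat6a WT and -1.35 ± 0.03 (n = 3) in Kat6a KO (exact permutation test, two-sided, p = 0.161). Other lists that may bear on stage were called as well (limma camera, preset correlation). Developmental timing (median -0.08) and proliferation (-0.06) were lower and oxidative phosphorylation (0.08) was higher, and none of these calls held with an estimated correlation. They do not separate stage from genotype either. A difference in stage was not tested for the epicardium and macrophage lists and stays open there. The labels give no somite counts, litters or dissection times that could settle the part of stage or of tissue handling.

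Of the changed genes with a known position, 0.498% start within 5 Mb of Kat6a, a window that may hold only some variants linked to the targeted allele. In that window 2 of 61 tested genes changed (3.28%), against 2.73% elsewhere (Fisher's exact test, p = 0.684). The odds ratio was 1.21 with a confidence interval of 0.142 to 4.59, too wide to exclude an excess near Kat6a. Changed genes lay next to each other more often than chance gives, in 21 pairs against a mean of 10.9 in 10000 permutations (one-sided permutation p = 0.0024). Of the 21 pairs, 13 changed in the same direction. With 217 changed genes higher and 186 lower, many pairs agree in direction by chance, and the 13 were not tested against that.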
